A study of Mus musculus with 6 samples.

How the data were processed

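Cheek skin of 3 C57BL/6 mice aged 6 to 8 weeks was profiled by RNA sequencing in 6 libraries, 1 per cheek. Per the labels' protocols, the right cheek was wiped with an acetone and ether mixture for 30 s and then with water for 30 s (AEW, a model of dry, itching skin), and the left cheek with water alone for 60 s (vehicle). Treatment was repeated over 12 days and tissue was taken on day 12. The groups therefore hold 3 libraries each, and the side of the face coincides with the treatment in every mouse. Libraries were made from poly(A)-selected RNA and read as single ends of 50 bases, per the labels. Whether the libraries keep the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

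The values were made by the authors before deposit. The deposited table gives, per the file headers, estimated counts, FPKM and TPM made by the authors for 19309 genes in each library. The estimated counts are fractional for 53.9% to 57.2% of the genes in a library. Their totals were alike across libraries and do not show whether they were scaled between libraries before deposit. The file headers name the deposited FPKM and TPM values, units that by definition scale counts for gene length and library size, and how the authors computed them is not given in the sources used here. The deposited table also holds the authors' mean of each measure per group. The submitters' processing notes name HISAT and the GRCm39 build. The counting tool, its version and the annotation are not given in the sources used here. No genome coordinates are printed, because the annotation at hand belongs to another build, and genes are identified by the symbol and the NCBI gene number in the table. A fractional estimate can divide reads among near-identical genes, so the values of single members of the stefin A, Sprr2, Lce3, Krt6, gasdermin C and haemoglobin families are uncertain.

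Estimated counts were rounded to whole numbers before testing. Library totals ran from 18449207 to 19506491. Genes were kept with the filterByExpr rule of edgeR at a minimum count of 10, which left 15109 genes holding at least 99.94% of the counts of each library. Counts were scaled with TMM factors between 0.973 and 1.05. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with group as the single term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F value, and confidence intervals are at 95%. Levels are TMM-scaled CPM, counts divided by the scaled library size, with the SD over 3 libraries. Intervals of ratios of counts are exact binomial and cover counting error only. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of at least 19.94), so none was counted as a copy.

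The test was tried on simulated counts of 14947 genes that passed the filter, with 200 genes changed. The means were those of the vehicle libraries, and the library sizes and trended dispersions those of the AEW and vehicle comparison. Neither a mouse effect nor a larger spread in the AEW group was simulated, so recovery in the data can be lower. The fit with group alone recovered 15.2% of the genes changed 1.5 fold, 68.7% of those changed 2 fold and 96.9% of those changed 4 fold, with 13 of its 132 calls false. A simulated shift of 1.5 fold in the cell division list was called with the preset and with the estimated correlation, with 0 of the other lists called. The genes were drawn independently of one another, so this does not show how the list tests behave when genes are correlated.

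Both cheeks of a mouse carry the same number in the labels, so the numbers pair the libraries by animal. The deviations from the group means correlated at -0.244, -0.165 and -0.246 within the 3 mice across genes, and between 0.0496 and 0.181 between cheeks of different mice. The main fit left out the pairing by mouse. With negative correlations within mice it can understate the spread of the AEW to vehicle difference, so its p-values can be too small. A fit with the mouse as a block was run beside the main one, and it called 888 genes against 1760.

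Before the data were examined, 15 theme lists and 20 cell type marker lists were fixed. Each list with at least 5 tested genes, 33 in all, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 33 lists, then with an estimated correlation and with fry. Counts of members past the threshold are given over all genes and adjusted over the list alone. Named genes followed a rule fixed at the same time. It took Mmp9, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, the same direction in all 3 mice and a symbol that is not a predicted model. It then took the 4 members of each theme list and the 2 members of each marker list with the smallest p. Other genes are named where said, and 4 genes that the rule takes are not reported here.

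Other settings chosen at that time were the mouse as a block, DESeq2 1.42.0, RLE size factors, library size alone, no filter beyond genes at 0 throughout, at least 50 counts in at least 3 libraries, each library left out in turn, and limma with a trend on log2(TPM + 1). Leaving out mouse 1 and leaving the muscle markers out of the counts were added after the data were seen.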

Results

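RNA was sequenced from the cheek skin of 3 mice after 12 days of treatment. In each mouse the right cheek received acetone and ether followed by water (AEW), a treatment that strips lipids from the skin surface and gives a dry, itching skin, and the left cheek received water alone (vehicle). The series title places matrix metalloproteinase 9 at the centre of the study, and the comparison asked how gene expression in AEW skin differed from that in vehicle skin. Library totals were 18522830, 18449207 and 18498723 estimated counts for vehicle replicates 1 to 3 and 19221850, 19506491 and 19120764 for AEW replicates 1 to 3. The replicate number is the mouse number. Replicates were separate animals, and AEW was always on the right side.

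AEW skin showed higher transcripts of stress keratins, small proline-rich proteins, Lce3 late cornified envelope proteins and cell division genes, and lower transcripts of skeletal muscle. Of 15109 tested genes, 733 were higher and 1027 lower at an adjusted p under 0.05 in the edgeR quasi-likelihood test. Of these, 314 were at least 2 fold higher and 342 at least 2 fold lower, and 732 of the 733 and all 1027 had the same direction in all 3 mice. That agreement follows largely from choosing the genes on these same libraries, so it is little support by itself. With the mouse as a block, 300 were higher and 588 lower, of which 267 and 561 were also called without it. The higher counts fell to 33 without vehicle replicate 1, 376 without vehicle replicate 2, 23 without vehicle replicate 3, 175 without AEW replicate 2 and 346 without AEW replicate 3, and reached 1197 without AEW replicate 1. The lower counts were 148 without vehicle replicate 1, 117 without vehicle replicate 3, 258 without AEW replicate 2 and 654 without AEW replicate 3. None of the 1760 changed genes took the opposite sign in any of these fits, which reuse the libraries behind the calls, so this adds little support.

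Mmp9 (gene 17395), which encodes a gelatinase that cleaves basement membrane collagen, stood at 7.73 ± 1.51 CPM in vehicle skin and 8.88 ± 4.63 CPM in AEW skin (SD, n = 3 each). Its log2 fold change was 0.20 with a standard error of 0.42 and a 95% interval from -0.80 to 1.20, and the difference was within the spread between replicates (adjusted p = 0.785). The estimated counts in vehicle skin were 161, 111 and 151 in mice 1, 2 and 3, and those in AEW skin were 72, 209 and 234. The AEW to vehicle ratio of Mmp9 was thus 0.407 in mouse 1 (95% exact binomial interval 0.304 to 0.541), 1.83 in mouse 2 (1.45 to 2.33) and 1.44 in mouse 3 (1.17 to 1.78). The authors' deposited table gives mean FPKM values of 2.85 for AEW and 2.44 for vehicle. Without AEW replicate 3 the log2 fold change was -0.091 (adjusted p = 0.921). Without AEW replicate 1 it was 0.57 (adjusted p = 0.0985). With mouse 1 left out and the mouse as a block, a setting added after the data were seen, it was 0.70 (adjusted p = 0.029).

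**Figure D1:**
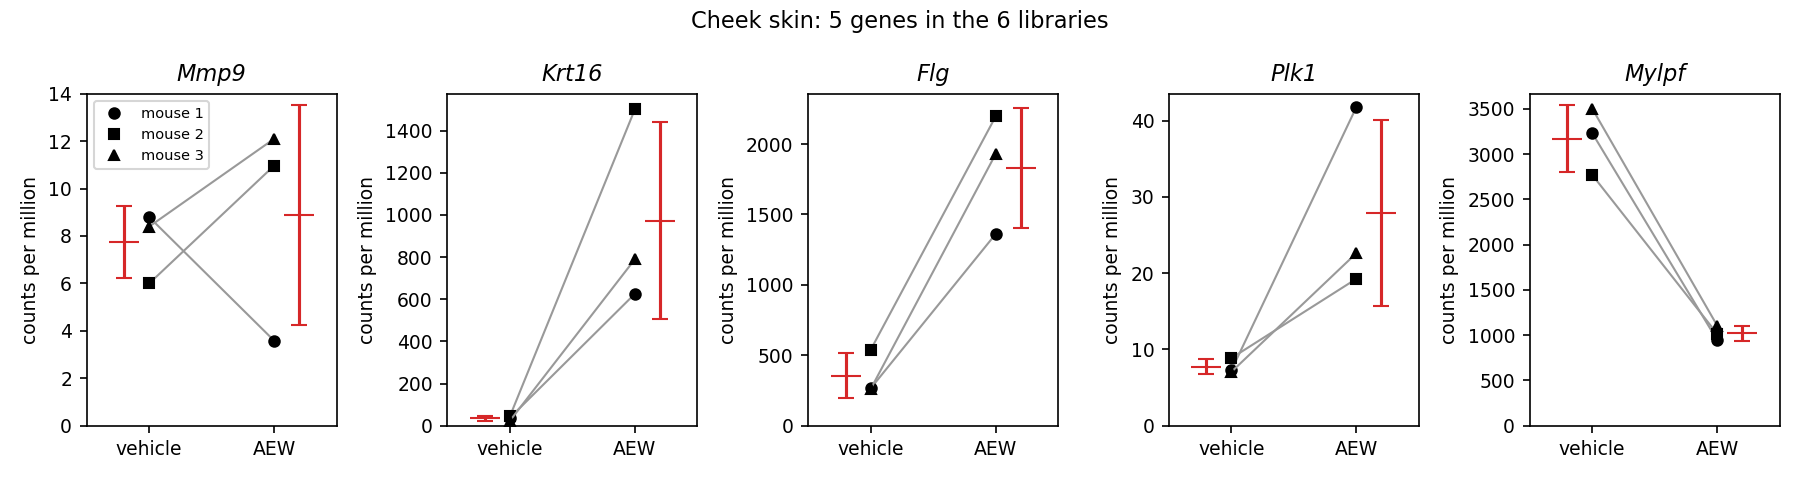
Scaled counts (CPM) of Mmp9, Krt16, Flg, Plk1 and Mylpf in the 6 libraries, with a line joining the cheeks of each mouse and red bars for the group mean and SD (n = 3). The lines of Mmp9 cross, whereas Krt16, Flg and Plk1 are higher and Mylpf is lower with AEW in each of the 3 mice.

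Among the matrix metalloproteinases and their inhibitors, 3 of 21 tested members were higher and 2 lower, and 4 and 2 when adjusted over the list alone. Timp1 (gene 21857), an inhibitor of these enzymes, rose from 7.90 ± 2.31 to 24.3 ± 7.40 CPM, a log2 fold change of 1.62 ± 0.29 (SE, adjusted p = 0.021). Mmp10 rose by a log2 fold change of 2.80 ± 0.64 (SE, adjusted p = 0.0381). Timp3 and Timp4 fell, with log2 fold changes of -0.73 and -1.27. The other member that was higher was Mmp14, chosen after its values were seen, at a log2 fold change of 0.70. The list did not pass the camera test (adjusted p = 0.352, and adjusted p = 0.827 with an estimated correlation), but did with mouse 1 left out and the mouse as a block (adjusted p = 0.0405). No member was called without vehicle replicate 1, vehicle replicate 3 or AEW replicate 2, 0 members were higher without vehicle replicate 2, and 1 was lower without AEW replicate 3.

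The stress keratins and related barrier proteins, which are induced in wounded or inflamed epidermis, gave the greatest shift of any tested list. Of 28 tested members 21 rose and 0 fell, and 25 rose when adjusted over the list alone, with a median log2 fold change of 4.30. Krt16 (gene 16666), a keratin of hyperproliferative epidermis, rose from 35.2 ± 10.9 to 973 ± 465 CPM, a log2 fold change of 4.79 ± 0.42 (SE, adjusted p = 0.00478). The gap junction gene Gjb2 (gene 14619) rose from 25.8 ± 3.16 to 182 ± 33.2 CPM. Lce3d and Lce3e, late cornified envelope genes, rose by log2 fold changes of 5.28 ± 0.47 and 5.10 ± 0.46. The list passed camera (adjusted p = 1.52e-38), but not with an estimated correlation (adjusted p = 0.275). The count of higher members was 9 without vehicle replicate 1 and 6 without vehicle replicate 3, and 1 member was lower without AEW replicate 2.

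Genes with the 10 largest rises came largely from the same protein families. Spink7, a serine protease inhibitor gene, had 2 estimated counts over the vehicle libraries and 622 over the AEW libraries, a ratio of 291 (95% interval 80.3 to 2410). Csta3, a cystatin relative, had 1 and 263, a ratio of 246 (43.8 to 9770). Krt6b had a log2 fold change of 7.28 ± 1.20 (SE), with an adjusted p of 0.017 that became 0.0576 with the mouse as a block. Lce3b, Stfa2, Sprr2f, Lce3a, Stfa1, Lce3f and Sprr2d had log2 fold changes from 5.58 to 6.25, with vehicle means from 0.0923 to 1.22 CPM.

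Proteins of the cornified envelope and of terminal differentiation rose in part. Of 47 tested members 12 rose and 1 fell, and 17 and 2 did so adjusted over the list alone. Flg (gene 14246), which encodes filaggrin, rose from 355 ± 160 to 1830 ± 426 CPM, a log2 fold change of 2.37 ± 0.34 (SE, adjusted p = 0.0125). Casp14, a caspase of cornification, and Tgm3, an epidermal transglutaminase, rose by log2 fold changes of 2.17 ± 0.28 and 2.00 ± 0.28. Lce1m, of the constitutive late envelope genes, fell from 1331 ± 164 to 614 ± 81.5 CPM (log2 fold change -1.12, adjusted p = 0.011). The list passed camera (adjusted p = 9.4e-07), but not with an estimated correlation (adjusted p = 0.758). The count of higher members was 0 without vehicle replicate 1 or 3, 6 without AEW replicate 2 or 3, and 22 without AEW replicate 1, and that of lower members was 0 without vehicle replicate 3 and 2 without AEW replicate 3.

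Of 20 tested antimicrobial and alarm proteins of the epidermis 9 rose and 1 fell, and 11 and 1 did so adjusted over the list alone. With the mouse as a block 5 rose and 0 fell. Stfa3 (gene 20863), a stefin that inhibits cysteine proteases, rose from 3.21 ± 1.54 to 138 ± 67.1 CPM, a log2 fold change of 5.41 ± 0.50 (SE, adjusted p = 0.00518). Stfa2 and Stfa1 rose by 5.88 and 5.62, and Wfdc12 by 5.13 on the log2 scale. These stefins are near-identical copies, so their separate values are uncertain. The list passed camera (adjusted p = 6e-10), but not with an estimated correlation (adjusted p = 0.722). The count of higher members was 3 without vehicle replicate 1, 6 without vehicle replicate 2, 3 without vehicle replicate 3, 14 without AEW replicate 1 and 5 without AEW replicate 2, and 0 members were lower in any of the 6 fits that left out a library.

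Of 36 tested genes for barrier ceramides and fatty acids 7 rose and 1 fell (13 and 2 adjusted over the list alone). Elovl3, a fatty acid elongase, rose from 227 ± 46.6 to 499 ± 110 CPM, and Sptlc2, of the first step of sphingolipid synthesis, rose by a log2 fold change of 0.49 ± 0.09 (SE, adjusted p = 0.0209). Scd2 rose by 0.84 on the log2 scale, and Ppara, a nuclear receptor of lipid metabolism, fell by 0.66. Of 25 tested genes for cholesterol synthesis and uptake 5 rose and 0 fell (12 and 0 adjusted over the list alone), and 3 rose with the mouse as a block. Ebp, a sterol isomerase gene, rose from 56.8 ± 6.13 to 83.3 ± 8.48 CPM (log2 fold change 0.55 ± 0.12, SE, adjusted p = 0.0319). Srebf2 and Dhcr7 had log2 fold changes of 0.45 and 0.91, with adjusted p of 0.0643 and 0.117 with the mouse as a block. Camera called both lists (adjusted p = 5.31e-05 and 1.19e-05), but with an estimated correlation each had an adjusted p of 0.75. Neither list had a higher member without vehicle replicate 1 or vehicle replicate 3, and each had 1 without AEW replicate 2 or AEW replicate 3. Without AEW replicate 1 the counts of higher members were 21 and 8, and without vehicle replicate 2 the first list had 3 higher and 4 lower. That list had 0 lower without vehicle replicate 3.

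Tight junction, hydration and hyaluronan genes included 6 higher and 0 lower of 21 tested (9 and 0 adjusted over the list alone), and 3 higher with the mouse as a block. Has3, a hyaluronan synthase, rose from 3.16 ± 0.62 to 12.7 ± 3.25 CPM (log2 fold change 2.01 ± 0.25, SE, adjusted p = 0.0102). Cemip, which takes part in hyaluronan breakdown, rose by a log2 fold change of 3.45 ± 0.52, and the water channel gene Aqp3 rose from 165 ± 47.4 to 540 ± 242 CPM. Aqp5 had a log2 fold change of 1.49, with an adjusted p of 0.0662 with the mouse as a block. Camera called the list (adjusted p = 0.0117), but not with an estimated correlation (adjusted p = 0.75), on the deposited TPM values (adjusted p = 0.0876) or without AEW replicate 3 (adjusted p = 0.053). The count of higher members was 0 without vehicle replicate 1, 4 without vehicle replicate 2, 1 without vehicle replicate 3, 10 without AEW replicate 1, 2 without AEW replicate 2 and 3 without AEW replicate 3.

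Of 43 tested itch mediators and receptors 3 rose and 1 fell, over all genes and adjusted over the list alone, and 1 and 0 did so with the mouse as a block. Klk8, an epidermal serine protease, rose from 89.7 ± 21.4 to 249 ± 49.8 CPM (log2 fold change 1.47 ± 0.21, SE, adjusted p = 0.0126). Nppb, the natriuretic peptide B gene, and Klk6 each had a log2 fold change of 3.38, with adjusted p of 0.0502 and 0.13 with the mouse as a block. Mrgprb2, a mast cell receptor, had a log2 fold change of -0.79, with an adjusted p of 0.088 with that block. Camera gave an adjusted p of 0.0354, but 0.827 with an estimated correlation, 0.0891 without a low-count filter, 0.0876 on the deposited TPM values, 0.104 without vehicle replicate 3, 0.22 without AEW replicate 2 and 0.108 without AEW replicate 3. The count of higher members was 0 without vehicle replicate 1 or 3, 2 without vehicle replicate 2, AEW replicate 2 or AEW replicate 3, and 7 without AEW replicate 1, and 0 members were lower without vehicle replicate 1, vehicle replicate 3 or AEW replicate 2.

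Among 34 tested cytokines and chemokines 5 rose and 1 fell (5 and 4 adjusted over the list alone). Cxcl1, a neutrophil attractant, rose from 0.603 ± 0.15 to 3.25 ± 0.87 CPM (log2 fold change 2.42 ± 0.33, SE, adjusted p = 0.0121). Ccl20 and Il1f6, an interleukin 36 gene, rose by log2 fold changes of 2.87 and 1.80. Ccl27a, a chemokine of resting keratinocytes, had a log2 fold change of -0.97 with an adjusted p of 0.0207, which became 0.0534 with the mouse as a block. Camera did not call the list (adjusted p = 0.0776, and adjusted p = 0.827 with an estimated correlation), though it did with the mouse as a block (adjusted p = 0.00582), with no low-count filter (adjusted p = 0.0127), without vehicle replicate 1 (adjusted p = 0.0181) and without AEW replicate 1 (adjusted p = 0.000145). With mouse 1 left out, as chosen after the data were seen, it had an adjusted p of 1.02e-05. The list's median was -0.59 in mouse 1, 0.56 in mouse 2 and 0.85 in mouse 3. The count of higher members was 0 without vehicle replicate 1 or 3, 1 without vehicle replicate 2, AEW replicate 2 or AEW replicate 3, and 9 without AEW replicate 1, and that of lower members was 0 without vehicle replicate 3 or AEW replicate 2 and 2 without AEW replicate 3.

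Cell division genes rose broadly. Of 35 tested members 26 rose and 0 fell, and all 35 rose adjusted over the list alone, with a median log2 fold change of 1.35. With the mouse as a block the counts were 6 over all genes and 33 adjusted over the list alone. Plk1 (gene 18817), a mitotic kinase, rose from 7.73 ± 0.98 to 27.9 ± 12.2 CPM (log2 fold change 1.85 ± 0.30, SE, adjusted p = 0.017). Ccnb1, the cyclin B1 gene, and Ube2c, a ubiquitin-conjugating enzyme gene of mitosis, rose by log2 fold changes of 1.52 and 1.62. Cdc20 had a log2 fold change of 1.49, with an adjusted p of 0.0532 with the block. The list passed camera (adjusted p = 1.16e-23), but not with an estimated correlation (adjusted p = 0.722). The list's median was 2.01 in mouse 1, 0.71 in mouse 2 and 1.07 in mouse 3. The count was 0 without vehicle replicate 1 or 3, 10 without vehicle replicate 2, 12 without AEW replicate 2, 17 without AEW replicate 3 and 29 without AEW replicate 1.

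Of 44 tested matrix genes 2 rose, over all genes and adjusted over the list alone. Tnc, the tenascin C gene, rose from 20.9 ± 1.63 to 97.3 ± 34.7 CPM (adjusted p = 0.0089), and Col18a1 rose by a log2 fold change of 0.59 ± 0.10. Fbn2 and Col7a1 had log2 fold changes of 2.82 and 0.65 with adjusted p of 0.118 and 0.122, and of 0.72 and 0.37 without AEW replicate 1 (adjusted p = 0.25 and 0.196). DESeq2 gave Fbn2 an adjusted p of 0.00943. Camera called the list (adjusted p = 0.0117), but not with an estimated correlation (adjusted p = 0.827), without AEW replicate 1 (adjusted p = 0.414), without vehicle replicate 2 (adjusted p = 0.0698) or with mouse 1 left out (adjusted p = 0.065), a setting added after the data were seen. Of the 30 tested oxidative stress and xenobiotic enzymes 4 rose and 6 fell (5 and 8 adjusted over the list alone), and 1 and 3 did so with the mouse as a block. Slc7a11, a cystine transporter gene, rose by a log2 fold change of 2.43 ± 0.41, whereas Aldh1a1 fell from 122 ± 21.5 to 56.5 ± 5.26 CPM and Gstm1 fell by 0.72 on the log2 scale. Cyp2e1 had a log2 fold change of -1.70 and an adjusted p of 0.0502 with the block. Camera did not call this list (adjusted p = 0.908, and adjusted p = 0.963 with an estimated correlation). Neither list had a called member without vehicle replicate 1 or vehicle replicate 3. Without AEW replicate 2 the matrix list had 1 higher member, and the enzyme list had 1 higher and 1 lower. Without vehicle replicate 2 each list had 1 higher member, and without AEW replicate 3 the matrix list had 1 lower and the enzyme list 1 higher and 4 lower.

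Among 23 tested immediate early genes 1 rose and 2 fell, over all genes and adjusted over the list alone. Atf3, a stress-induced transcription factor, fell from 39.5 ± 10.9 to 10.1 ± 1.56 CPM (log2 fold change -1.97 ± 0.22, SE, adjusted p = 0.00774) and Klf2 fell by 0.73 on the log2 scale. Atf3 was called in each of the 6 fits that left out a library, Klf2 in 3 and Egr3 in 0, while 2 other members were higher without AEW replicate 1. Egr3 had a log2 fold change of 0.58 with an adjusted p of 0.108 with the mouse as a block, and Fosl1 one of 1.97 with an adjusted p of 0.0857, which was 0.0351 without AEW replicate 1 and 0.0121 with DESeq2. The list's median was -0.02 while camera gave the direction up (adjusted p = 0.933, and adjusted p = 0.981 with an estimated correlation). Of 26 tested interferon-stimulated genes 0 passed the edgeR threshold, over all genes or adjusted over the list alone, and 0 did so with DESeq2 or on the deposited TPM values with limma, while 1 had an unadjusted p under 0.05. Irf1, Xaf1, Ifit2 and Ifih1 had log2 fold changes of -0.54, -0.56, -0.63 and -0.31 with adjusted p of at least 0.102 (camera adjusted p = 0.265, and adjusted p = 0.963 with an estimated correlation). Camera called that list down without vehicle replicate 2 (adjusted p = 0.0324), vehicle replicate 3 (adjusted p = 0.0182) or AEW replicate 2 (adjusted p = 0.0144), and up with mouse 1 left out (adjusted p = 0.00765), a setting added after the data were seen, in which 3 members were higher, and 8 with the block in addition. The list's medians were -1.57, 0.76 and -0.0044 in mice 1, 2 and 3. Of 31 tested growth factor and Wnt genes 1 rose, over all genes and adjusted over the list alone. It was Foxn1, a transcription factor of hair and epidermal differentiation, at a log2 fold change of 0.88 ± 0.16 (SE, adjusted p = 0.0203), and it was not called without any one of vehicle replicates 1 to 3 or AEW replicate 3. Fzd10, Fgf18 and Wnt4 had log2 fold changes of 0.70, -1.12 and 0.34 with adjusted p of 0.0522, 0.059 and 0.08 (camera adjusted p = 0.0917, and adjusted p = 0.827 with an estimated correlation). DESeq2 called these 3 genes (adjusted p = 0.00804, 0.00446 and 0.045). Fzd10 was also called with the stricter filter (adjusted p = 0.0497) and, at a log2 fold change of 0.46, without AEW replicate 1 (adjusted p = 0.0339), and Fgf18 without AEW replicate 3 (adjusted p = 0.0388). Camera called that list without AEW replicate 2 (adjusted p = 0.000218). It had 3 higher and 2 lower members without AEW replicate 1, and 1 lower without AEW replicate 3.

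Skeletal muscle transcripts fell by similar factors in all 3 mice. Of 23 tested muscle fibre markers 21 fell and 0 rose, and all 23 fell adjusted over the list alone. Their median log2 fold change was -1.34, and the medians were -1.47, -1.22 and -1.32 in mice 1, 2 and 3. Mylpf (gene 17907), a fast myosin light chain, fell from 3169 ± 371 to 1021 ± 80.8 CPM (log2 fold change -1.63 ± 0.14, SE, adjusted p = 0.00478), and Myl1 fell by 1.56 on the log2 scale. The 23 markers held 4.93% ± 0.85 of all counts in vehicle libraries and 2.03% ± 0.37 in AEW libraries (SD, n = 3 each). Camera called the list (adjusted p = 6.47e-35), but not with an estimated correlation (adjusted p = 0.275). The count of lower members was 10 without vehicle replicate 1, 7 without vehicle replicate 3 and 10 without AEW replicate 2.

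The 10 largest falls also held muscle genes. Mybph and Xirp1, of the contractile apparatus, fell by 2.10 and 2.02 on the log2 scale, and Csrp3, a Z-disc protein gene, fell from 282 ± 15.4 to 72.0 ± 23.0 CPM. Ifitm6 fell from 17.8 ± 1.12 to 2.10 ± 0.69 CPM (log2 fold change -3.09 ± 0.23, SE, adjusted p = 0.00478). Apol7a, Tceal7, Dupd1 and Atf3 fell by 2.91, 2.13, 2.03 and 1.97 on the log2 scale. Myl2, a slow myosin light chain, and Pon1, a paraoxonase gene, had log2 fold changes of -3.33 and -2.21, with adjusted p of 0.0535 and 0.0553 with the mouse as a block, and Myl2 was called in 0 of the 6 fits that left out a library.

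**Figure D2:**
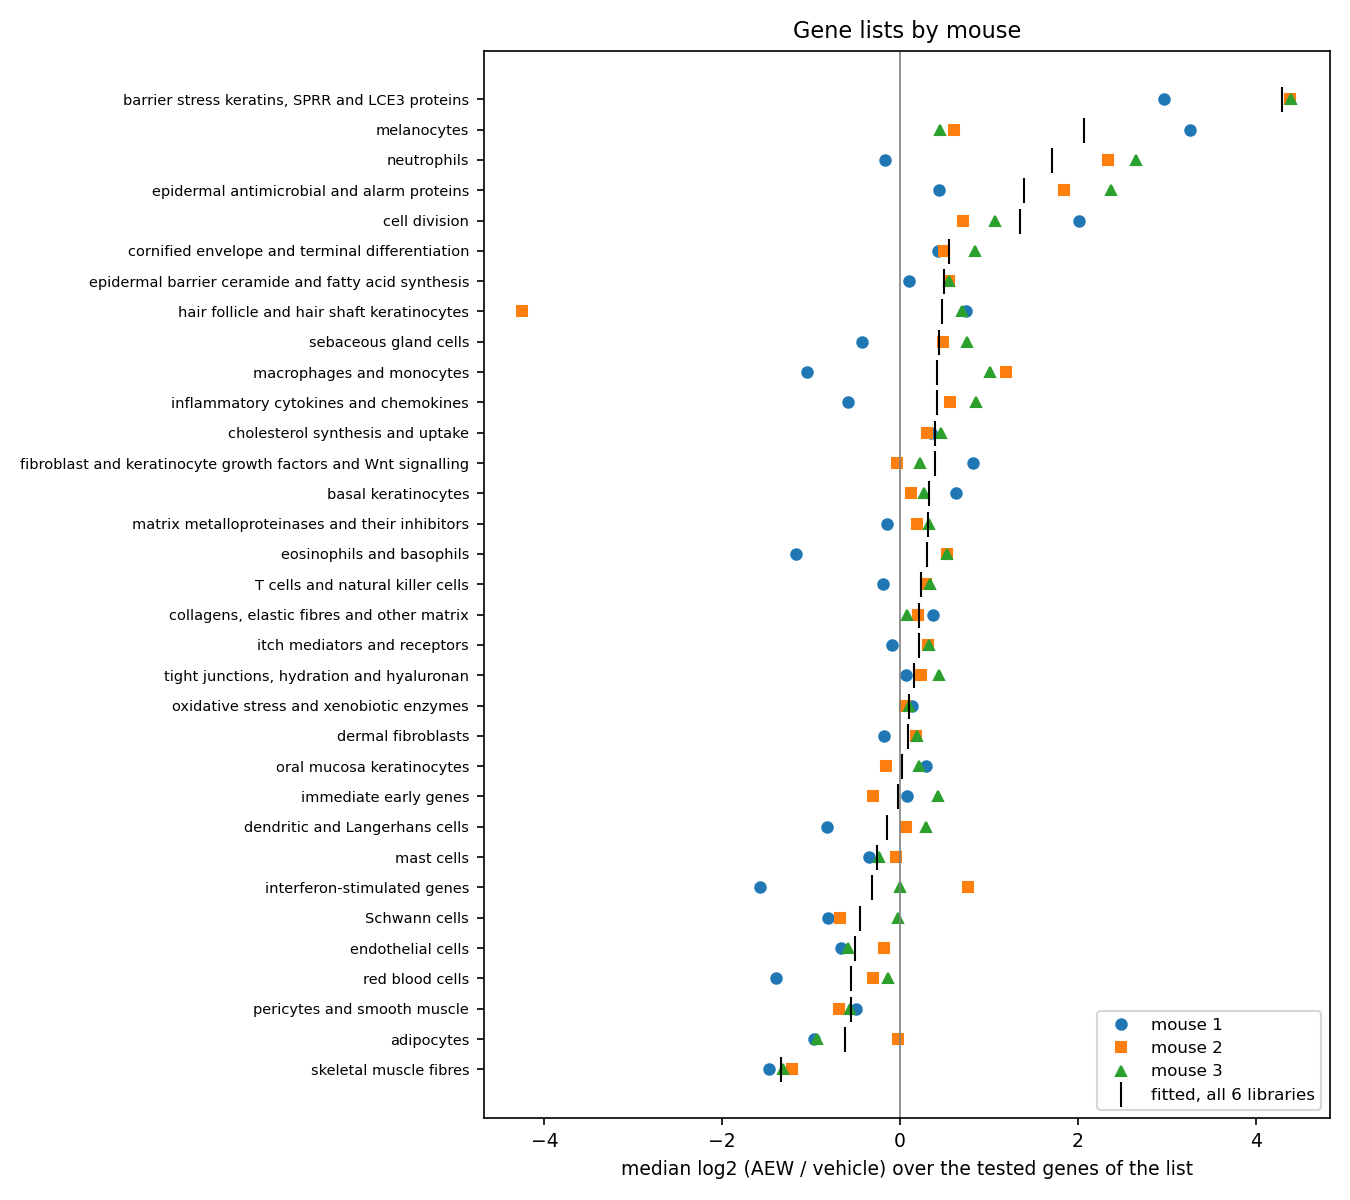
Median log2 ratio of AEW to vehicle over the tested genes of each of the 33 lists, by mouse (coloured points), with the median of the fitted log2 fold changes as a black tick. The muscle list lies between -1.47 and -1.22 in the 3 mice, whereas the macrophage list is at -1.05 in mouse 1 and at 1.19 and 1.01 in mice 2 and 3.

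Markers of vessels, fat and nerve were lower or not called. Of 12 tested pericyte and smooth muscle markers 4 fell (7 adjusted over the list alone). Des, which skeletal muscle also expresses, fell from 1676 ± 305 to 708 ± 105 CPM, and Mylk fell by 0.79 on the log2 scale. Of 14 endothelial markers 3 fell (11 adjusted over the list alone), and 1 did so with the mouse as a block. Emcn fell by 0.60 on the log2 scale (adjusted p = 0.0174), and Tie1 had a log2 fold change of -0.54 with an adjusted p of 0.0692 with the block. Of 14 adipocyte markers 2 fell (10 adjusted over the list alone), Cfd and Adipoq, with log2 fold changes of -1.06 and -0.94, and 0 did so with the block (adjusted p of 0.0807 and 0.114). Of 13 Schwann cell markers 1 was lower (0 adjusted over the list alone). It was Cdh19 at -0.62, with an adjusted p of 0.109 with the block. Camera called these 4 lists (adjusted p = 6.35e-05, 0.000101, 4.06e-05 and 0.0184), but with an estimated correlation gave adjusted p = 0.275, 0.75, 0.75 and 0.827. Without vehicle replicate 1, vehicle replicate 3 and AEW replicate 2 the pericyte list had 0, 1 and 2 lower members. The endothelial list had 6 without vehicle replicate 2 and 1 without AEW replicate 2 or 3, and the adipocyte list had 10 without vehicle replicate 2, 1 without AEW replicate 1 and 0 without AEW replicate 2 or 3. The Schwann list had 3 lower without AEW replicate 3 and 0 in each of the other fits that left out a library. No endothelial or adipocyte marker was called without vehicle replicate 1 or vehicle replicate 3, and the Schwann list lost its camera call without vehicle replicate 2, AEW replicate 1 or AEW replicate 2 (adjusted p = 0.0777, 0.0987 and 0.0527), and with mouse 1 left out (adjusted p = 0.134), as chosen after the data were seen.

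Keratinocyte and gland markers showed single changes, none of which was called without vehicle replicate 1 or vehicle replicate 3. Krt14, the keratin of basal keratinocytes, rose from 2799 ± 650 to 5480 ± 895 CPM, as 1 of 10 basal markers (2 higher and 1 lower adjusted over the list alone), and Krt15 had a log2 fold change of -0.76 (adjusted p = 0.0506, but 0.0488 without a low-count filter, 0.0465 with the stricter one and 0.00152 with DESeq2). Camera gave the basal list an adjusted p of 0.0776 (adjusted p = 0.827 with an estimated correlation), against 0.0421 with the mouse as a block and 0.0084 without vehicle replicate 2. No basal marker was called without AEW replicate 2 or AEW replicate 3. Of 29 hair follicle markers 2 rose, over all genes and adjusted over the list alone, Krt79 and Krt84, by log2 fold changes of 0.70 and 2.52. That list had a median of 0.47 and a mean of 0.37 while camera gave the direction down (adjusted p = 0.908, and adjusted p = 0.981 with an estimated correlation), and up without AEW replicate 2 (adjusted p = 0.000426). It had 1 higher member without vehicle replicate 2, 0 called without AEW replicate 2, and 0 higher and 2 lower without AEW replicate 3, and its medians were 0.74, -4.25 and 0.70 in mice 1, 2 and 3. Of 14 sebaceous markers 2 rose and 1 fell (2 and 3 adjusted over the list alone), and 1 and 0 were called with the mouse as a block. Elovl3 rose by 1.13, Fabp5 had a log2 fold change of 1.08 with an adjusted p of 0.0571 with the block, and camera gave an adjusted p of 0.331 (adjusted p = 0.827 with an estimated correlation). Camera called the sebaceous list without AEW replicate 1 (adjusted p = 0.00346), with 6 higher and 1 lower, and with mouse 1 left out, as chosen after the data were seen (adjusted p = 9.26e-07), with 7 higher and 1 lower. It had 1 higher and 1 lower without vehicle replicate 2, 0 called without AEW replicate 2, and 0 higher and 2 lower without AEW replicate 3. Of 6 oral mucosa markers 0 passed in edgeR, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and 1 passed with DESeq2 and with limma on TPM. Tmprss11d had a log2 fold change of 2.85 (adjusted p = 0.0635, and adjusted p = 0.0362 with the block), which was 4.58 without vehicle replicate 2 (adjusted p = 0.0263), and Krt78 one of 0.28 (adjusted p = 0.369), with camera at an adjusted p of 0.768 (adjusted p = 0.827 with an estimated correlation), and 1 member was higher without vehicle replicate 2. Of the salivary markers only 2 were tested, too few for camera. Amy1 fell by 1.28 on the log2 scale and Aqp5 was higher, also when adjusted over the list alone. Without vehicle replicate 2 or AEW replicate 3, or with the block, 1 was lower and 0 higher, and 0 were called without AEW replicate 2. Of 13 fibroblast markers 1 was higher, over all genes and adjusted over the list alone. It was Pdgfra at 0.51 (adjusted p = 0.0703 with the block), beside Mfap5 at -0.68 (adjusted p = 0.0746, but 0.0414 without vehicle replicate 2 and 0.0171 with DESeq2), with camera at an adjusted p of 0.812 (adjusted p = 0.963 with an estimated correlation). No fibroblast marker was called without AEW replicate 1 or AEW replicate 2, and 1 was lower and 0 higher without vehicle replicate 2. Of 8 melanocyte markers 0 passed in edgeR over all genes, and 4 were higher and 1 lower adjusted over the list alone. With an unadjusted p under 0.05 there were 6, and DESeq2 called 4 and limma on TPM 0. Pmel and Tyr had log2 fold changes of 2.76 and 2.84 (adjusted p = 0.0658 and 0.079), which were 1.27 and 1.38 without AEW replicate 1 (adjusted p = 0.0226 and 0.109), with camera at an adjusted p of 0.149 (adjusted p = 0.827 with an estimated correlation, and adjusted p = 0.0144 without AEW replicate 2). Without AEW replicate 1, 2 melanocyte markers were higher, against 0 with mouse 1 left out and 3 with the block in addition. Camera gave an adjusted p of 0.181 without AEW replicate 1 and 0.273 with mouse 1 left out, and the medians were 3.26, 0.61 and 0.45 in mice 1, 2 and 3.

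Immune cell markers differed between mice. Of 7 tested neutrophil markers 3 were higher and 1 lower (6 and 1 adjusted over the list alone), and 1 and 0 were called with the mouse as a block. S100a9, which keratinocytes also express under stress, had a log2 fold change of 3.59 (adjusted p = 0.0352, and adjusted p = 0.0709 with the block), and Il1r2 one of -0.51 (adjusted p = 0.0328, and adjusted p = 0.0854 with the block). Camera called the list (adjusted p = 0.0133), but not with an estimated correlation (adjusted p = 0.758), the stricter count filter (adjusted p = 0.0633) or the deposited TPM values (adjusted p = 0.0651), and 0 members were called without any one of vehicle replicates 1 to 3, AEW replicate 2 or AEW replicate 3. Of 20 macrophage markers 1 rose and 1 fell, over all genes and adjusted over the list alone. Arg1 fell by 1.01 on the log2 scale, and no member was called without vehicle replicate 1, vehicle replicate 3 or AEW replicate 2. Camera gave an adjusted p of 0.0969 (adjusted p = 0.827 with an estimated correlation), against 8.56e-05 without vehicle replicate 1 and 0.00346 without AEW replicate 1, and with mouse 1 left out, as chosen after the data were seen, 17 members were higher.

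Of 16 tested markers of T cells and natural killer cells 1 was higher and 1 lower (1 and 2 adjusted over the list alone), and 0 were called with the mouse as a block. Cd3g and Foxp3 had log2 fold changes of -0.74 and 1.41, with adjusted p of 0.0508 and 0.105 with the block, and camera gave an adjusted p of 0.915 (adjusted p = 0.981 with an estimated correlation). Of 11 mast cell markers 2 were lower, over all genes and adjusted over the list alone, Mrgprb2 and Gata2, and 0 with the block, where Gata2 had an adjusted p of 0.0666 (camera adjusted p = 0.265, and adjusted p = 0.827 with an estimated correlation). None of 15 dendritic and Langerhans cell markers, 6 eosinophil and basophil markers, 4 B cell markers and 7 red blood cell markers passed in edgeR, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 1, 1, 1 and 2 of them, and DESeq2 called 1 dendritic cell marker and 2 red blood cell markers as lower and 0 of the others, while limma on TPM called 0. Neither the T cell nor the mast cell list had a lower member without vehicle replicate 1, vehicle replicate 3 or AEW replicate 2, and the mast cell list had 1 without vehicle replicate 2 or AEW replicate 3. The T cell list had 2 higher members without AEW replicate 1 and 0 in each of the other fits that left out a library. Zbtb46 and Epcam had log2 fold changes of -0.64 and 0.36 (adjusted p = 0.0613 and 0.203), Prss34 and Il5ra -0.98 and 0.53 (adjusted p = 0.148 and 0.272), Jchain -0.84 (adjusted p = 0.272), and Hba-a1 and Hbb-bs -0.83 and -0.75 (adjusted p = 0.119 and 0.142). Camera gave the dendritic cell list an adjusted p of 0.881 and the eosinophil list one of 0.933, and each an adjusted p of 0.981 with an estimated correlation. With mouse 1 left out, as chosen after the data were seen, the eosinophil list had an adjusted p of 0.00607 and 3 higher members, and it had 1 without AEW replicate 1. The red blood cell list was called down (adjusted p = 0.0433), but not with an estimated correlation (adjusted p = 0.758), the stricter count filter (adjusted p = 0.0699) or the mouse as a block (adjusted p = 0.0886), nor without vehicle replicate 1 or 2 (adjusted p = 0.251 and 0.1) or AEW replicate 1 or 2 (adjusted p = 0.0987 and 0.0634), nor with mouse 1 left out (adjusted p = 0.264). B cells had too few tested genes for camera.

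Across the 33 lists tested, camera with the preset correlation called 16, none of which was called with an estimated correlation, where the smallest adjusted p was 0.275. The fry test called 2 of them, muscle fibres (adjusted p = 0.0427) and pericytes and smooth muscle (adjusted p = 0.0114), and 0 with the mouse as a block. Other groupings of the same 6 libraries gave up to 21 camera calls. Each of them mixed vehicle and AEW libraries, so they still carry part of the treatment difference and are no reference without it. The number of lists called was thus not highest for AEW against vehicle, and it adds no support.

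Some counts of list members also moved by over 1.5 times with the tool or the scaling. With DESeq2 the higher members were 20 for the cornified envelope, 15 for ceramides and fatty acids, 11 for cholesterol, 6 for growth factors and Wnt, 5 each for metalloproteinases, itch and matrix, 4 for sebaceous cells, 3 for immediate early genes and 2 for basal keratinocytes. The lower members were 10 for endothelial cells, 9 for adipocytes, 4 for the cornified envelope, 3 each for ceramides and fatty acids, itch and cytokines, 2 each for growth factors and Wnt, sebaceous cells and T cells, and 1 each for basal keratinocytes, hair follicles and fibroblasts. On the deposited TPM values the lower members were 2 for cytokines, 1 each for endothelial and mast cells and 0 for antimicrobial proteins and Schwann cells, and 0 immediate early genes were higher. The 1 lower sebaceous marker was not called with RLE size factors, library size alone or either other filter, nor was the 1 lower antimicrobial gene with library size alone or either other filter. With library size alone 0 immediate early genes and 2 basal markers were higher, and 0 Schwann cell and 1 mast cell markers were lower. With the stricter filter 2 growth factor and Wnt genes, 1 hair follicle marker and 0 T cell markers were higher, and 6 endothelial and 2 T cell markers were lower. Both other filters gave 2 lower cornified envelope genes and 1 lower basal marker.

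The libraries also differed within the AEW group. Transcripts of growing hair follicles and of pigment cells were high in AEW replicate 1, as found after the data were seen. Krt25, a keratin of the inner root sheath, was at 578, 1.89 and 118 CPM in AEW replicates 1, 2 and 3 and between 68.4 and 86.6 CPM in vehicle libraries. Dct, a pigment enzyme gene, was at 88.3, 15.2 and 19.0 CPM in AEW replicates and between 7.62 and 11.7 CPM in vehicle libraries. C1qb, a macrophage gene, was at 220, 94.7 and 81.2 CPM in vehicle replicates and at 95.7, 271 and 196 CPM in AEW replicates.

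**Figure D3:**
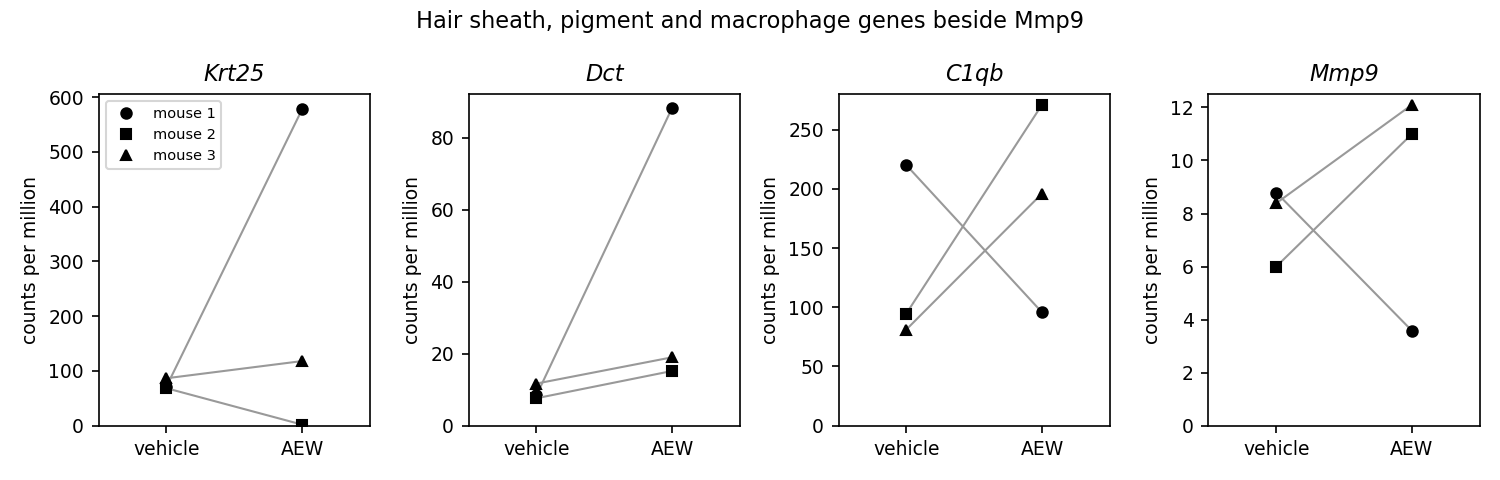
Scaled counts (CPM) of Krt25, Dct, C1qb and Mmp9 in each library, with a line joining the cheeks of each mouse. Krt25 and Dct are highest in the AEW library of mouse 1, at 578 and 88.3, and C1qb and Mmp9 are lower with AEW in mouse 1 and higher in mice 2 and 3.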

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

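The tests with mouse 1 or the muscle markers left out were chosen after the results were seen. Genes higher with AEW numbered 733, against 300 with the mouse as a replicate block, 1362 with DESeq2, 1922 with mouse 1 left out and the replicate block, and 23 to 1197 with each library left out in turn. Genes lower with AEW numbered 1027, against 588 with the replicate block, 666 on the deposited TPM values, 1588 with mouse 1 left out and the replicate block, and 117 to 1041 with each library left out. RLE factors, library size alone and both other filters kept both counts within 1.5 times. A fit on 5 libraries has fewer samples. It lost most calls without vehicle replicate 1 or vehicle replicate 3, and why these weighed more than the others was not tested. No changed gene took the opposite sign in any alternative that tested it, though all alternatives reuse the libraries behind the calls. Of 115 named genes 89 were called, 65 of them also with the replicate block and 16 in each of the 6 fits that left out a library; 1 other, Tmprss11d, was called with the block. The Mmp9 log2 fold change ran from -0.091 to 0.57 with each library left out, with its sign turned without AEW replicate 3, and was 0.07 with the replicate block. With mouse 1 left out it was 0.70 and past the threshold with the block (adjusted p = 0.029) and 0.68 without it (adjusted p = 0.0877), and over all alternatives the adjusted p ran from 0.029 to 0.99; the cause was not tested. The number of lists called was 16, against 17 with the replicate block, 0 with an estimated correlation, 2 with fry and 14 to 17 with each library left out. The list call with DESeq2 was not run, since camera does not take its fit. Besides the calls the report gives with the block, it changed no other list call.

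Directions turned as follows, given as the adjusted p in each setting, while ranges with each library left out cover all 6 fits, turned or not. For interferon-stimulated genes this was 0.00765 with mouse 1 left out, 0.0376 with the block in addition, and 0.104 without vehicle replicate 1, in a range of 0.0144 to 0.672 whose other fits kept the direction. For immediate early genes it was 0.838 with the stricter filter, 0.987 with fry, 0.967 with mouse 1 left out, and 0.129 to 0.75 with each library left out. Growth factor and Wnt genes turned with mouse 1 left out (0.901). Oral mucosa markers turned on TPM (0.968). Dendritic cell markers turned with mouse 1 left out (0.231, and 0.264 with the block) and ran from 0.35 to 0.957 with each library left out. T cell markers turned with the stricter filter (0.463) and on TPM (0.968), with 0.614 to 0.938. Eosinophil markers turned with library size alone (0.98) and on TPM (0.885), with 0.0987 to 0.905. Hair follicle markers ran from 0.000426 to 0.905 and fibroblast markers from 0.369 to 0.982 with each library left out. With mouse 1 left out, Ifit2 and Ifih1 had log2 fold changes of 0.022 and 0.00032. The cause was not tested for any of these. The self-test recovered 15.2% of genes changed 1.5 fold, so many changes of that size can be missed with 3 libraries per group.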

Other observations

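The gene families in this opening, and every test in this part apart from the regrouping of the libraries, were chosen after the results were seen. Of 8 families picked by symbol, kallikreins, serine proteases of the outer epidermis, had 5 of 9 tested members higher with AEW and 0 lower (median log2 fold change 1.46), with Klk13 at 3.60 ± 0.47 (SE, adjusted p = 0.0106). Of 7 gasdermins, which form membrane pores, 4 were higher, among them Gsdmc at 4.40 ± 0.66, and 1 was called with the mouse as a block. Of 6 cytosolic phospholipases A2, which release fatty acids from membrane lipids, 4 were higher, among them Pla2g4f, from 30.2 to 72.8 CPM. Of 8 stefins and cystatin A relatives 7 were higher, with Cstdc5 rising from 9.49 to 417 CPM. Gap junction genes had 3 of 13 higher, desmosomal cadherins 2 of 9 higher and clade B serpins 0 of 19 higher and 1 lower, or 2 higher and 1 lower with the mouse as a block.

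Subunits of the oxidative phosphorylation complexes went the other way. Of 88 tested subunits 26 were lower and 0 higher, with 82 of the 88 below 0 and a median log2 fold change of -0.31, and 9 were lower with the mouse as a block. The muscle isoforms Cox8b and Cox7a1 had log2 fold changes of -1.23 and -1.16, and Cox7c, which is expressed widely, one of -0.43. Skeletal muscle markers fell in the same libraries, with a median of -1.34, and how far the fall of the subunits reflects this was not tested. Camera called the families of kallikreins, gasdermins, phospholipases, stefins, oxidative phosphorylation, desmosomal cadherins and gap junctions with the preset correlation. It called none with an estimated one, where the smallest adjusted p was 0.125. The gap junction genes had a median log2 fold change of 0.0094, with 7 above 0 and 6 below. These families were picked on the same data and share members with the fixed lists, such as Gjb2, Stfa3 and Klk8. Their calls are therefore not separate support.

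Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 1760 changed genes and was the 1 split to give that many, and the highest of the others gave 0. For lists, 7 of the 10 splits gave at least the 16 calls of the real one, and the highest of the others gave 21. Among the 4 splits that part both cheeks of all 3 mice, the highest of the others gave 0 genes and 19 lists. With 10 splits a share under 0.05 cannot be reached. All the other splits also mix vehicle and AEW libraries in both sets, so the treatment difference adds to the spread within their sets. Neither their gene counts nor their list counts are therefore a reference free of the treatment.

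Skeletal muscle transcripts were lower with AEW in all 3 mice. The fall in the share of the 23 markers would raise every other gene by 0.0432 on the log2 scale. The rise would be 0.355 if all 7319 tested genes below 0 were muscle RNA. Both lie under the lower quartile of 1.45 in the barrier stress list, which argues against dilution as the source of that list's rises. For the cornified envelope, ceramide and cholesterol lists the lower quartiles were 0.0733, 0.223 and 0.185, above 0.0432 but under 0.355. Both rises come from unscaled counts, whereas the fold changes are TMM-scaled, which takes out a shift shared by most genes. The median of all tested genes was 0.0138. With the muscle markers left out of the counts, fold changes moved by a median of -0.0042. Camera then gave those lists adjusted p of 6.76e-07, 4.28e-05 and 1.02e-05. This argues against dilution by the 23 markers as the source of their camera calls. The bound does not decide for single smaller rises in those lists. A smaller share of muscle in the AEW tissue may account for part of the muscle fall. Of the 23 markers 100% lay below 0, with a median of -1.34 and an interquartile range of 0.192 on the log2 scale. Mybph, Xirp1, Csrp3 and Myl2 had log2 fold changes of -2.10, -2.02, -1.97 and -3.33. They were named as being among the largest falls, so lying beyond that median follows from the choice. Tnnt1 and Myoz2, other muscle genes, stood at -1.35 and -1.76. A difference in how deep the 2 cheeks were sampled stays open, because side and treatment coincide in every mouse, with adipocyte markers at a median of -0.614 but at -0.971, -0.0242 and -0.938 in mice 1, 2 and 3, where muscle was at -1.47, -1.22 and -1.32, and 0 of them called with the mouse as a block. An effect of AEW on muscle itself was not tested apart from these.

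Hair growth and pigment transcripts were high in the AEW library of mouse 1. In mouse 2 hair transcripts were low with AEW, with a list median of -4.25. Krt35 was at 0.263 CPM there against 10.4 to 15.1 CPM in vehicle libraries. The hair list held 0.23% of the counts of that library, against 0.159% to 0.214% in vehicle libraries. Nearly all of that share was Krt79, which was called higher with AEW and had 43427 of the library's 19506491 counts. In vehicle replicates 1, 2 and 3 Krt79 had 22486, 27026 and 20088 counts. The share therefore does not show that the other hair transcripts were kept. In mouse 3 the hair list median was 0.70, close to the 0.74 of mouse 1. Krt25 and Krt27 stood at 118 and 73.6 CPM in AEW replicate 3, and at most at 86.6 and 41.6 CPM in vehicle libraries. Whether pigment transcripts rose beyond mouse 1 stays open, as melanocyte medians were 0.61 and 0.45 in mice 2 and 3. Without the AEW library of mouse 1, 2 melanocyte markers were called higher, and camera gave the list an adjusted p of 0.181. With mouse 1 left out, 0 were called and camera gave an adjusted p of 0.273, while 3 were called with the block in addition. In the AEW library of mouse 1, 75% of the tested melanocyte markers, 6 of 8, were highest. That restates the pattern and leaves a growing stage of the hair cycle open as an explanation. The rise of cell division genes does not rest on that library alone, as their median log2 fold change without it was 0.913, with 29 of 35 members higher. Whether the treatment or the hair cycle of that cheek set the stage was not tested.

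Mmp9 was lower with AEW in mouse 1 and higher in mice 2 and 3. The upper bound of the ratio in mouse 1 was 0.541, which argues against counting error. Of 20 macrophage markers 90% had this pattern, against 12.6% of all tested genes, but their levels did not follow Mmp9 in vehicle replicate 1, where their median lay 1.16 above the other vehicle libraries on the log2 scale and Mmp9 0.306, while in AEW replicate 1 the values against the other AEW libraries were -1.07 and -1.66. Medians with the same signs were not particular to macrophages. In mice 1, 2 and 3 they were -0.166, 2.34 and 2.65 for the 7 tested of 18 neutrophil markers, among them S100a9, which stressed keratinocytes also express. They were -1.17, 0.525 and 0.533 for the 6 tested of 12 eosinophil and basophil markers, and -0.589, 0.562 and 0.851 for cytokines and chemokines. The share of members with the pattern was not computed for these other lists. A change in macrophage transcripts as the source of the Mmp9 pattern and a difference between mice in their response to AEW both stay open, the latter untested.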
